A study of Caenorhabditis elegans with 2 samples.

How the data were processed

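Binding sites of CEH-44, a homeobox protein of the CUT family, were measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caenorhabditis elegans. Per the labels, the endogenous ceh-44 gene had been tagged by CRISPR with TY1, EGFP and 3xFLAG sequences, and chromatin from whole larvae at the fourth larval stage (49 hours, synchronised through starved first-stage larvae) was sonicated to fragments of 200 to 800 bp and precipitated with an antibody against GFP. There were 2 biological replicates, 1 group, and no second condition. The replicate numbers come from the labels.

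All positions are on the ce11 assembly, per the labels and the descriptions deposited with the files. Each replicate had a ranked list of candidate peaks and a thresholded list of its own, made within that replicate. For the series, both replicates entered 2 ranked lists and 2 thresholded lists, a larger one and one the authors named conservative. The aligner, the peak caller and the read depth are not given in the sources used here. The thresholded lists were made with a control library among their inputs, per the deposited descriptions, and control data were not analysed here.

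The authors' deposited score for each peak is a scaled irreproducible discovery rate (IDR, an estimate of failure to repeat between the inputs compared). The deposited signal of each peak is the authors' own value, on a scale that is not stated. It was used only to rank, describe and compare peaks within a list, tests of median signal included, or to correlate lists. The ranked lists also hold the deposited −log10 of the global IDR. That is the expected share of peaks that do not repeat among those ranked at least as high, not a chance for each peak. Every peak of each thresholded list had a −log10 IDR of at least 2, an IDR of 0.01 or less. Some ranked peaks that pass this value are absent from the thresholded lists, for reasons not given in the sources used here. The conservative list's ranked file also gives the signal of each peak in both replicates, without saying which column is which replicate.

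Peaks were placed on the Ensembl annotation of WBcel235 (release 115), whose chromosome sequences are those of ce11. That annotation files the ceh-44 locus under the name of the overlapping gene cone-1, and the name ceh-44 was restored through the RefSeq locus tag. The names of the 612 tRNA genes came from RefSeq. A summit was assigned to a promoter when it lay from 1000 bp upstream to 200 bp downstream of a protein-coding gene's most upstream start. Otherwise it was assigned to an exon, an intron or intergenic sequence. Exons and introns were those of protein-coding genes, so a summit inside a noncoding gene could be classed as intronic or intergenic. A gene of any kind was called bound when a summit lay in that window around its start.

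The larger series list was the main list. Locations were compared with ranked peaks of the same file that did not pass, by Fisher's exact test, and with 1000 placements at random positions of the same chromosome. The 28 gene lists were compared with genes of the same class (coding or noncoding) that had any ranked summit in their window, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 28 lists. They covered pan-neuronal, neurotransmitter, neuropeptide, axon guidance, neuronal identity, CUT, ceh homeobox, nuclear hormone receptor, ciliary, chemoreceptor, muscle, pharynx, intestine, collagen, germline, sperm, ribosomal protein, histone, heat shock, translation factor, tRNA synthetase, respiratory chain, splicing, proteasome, vacuolar ATPase, tRNA, snoRNA with snRNA, and microRNA genes. For axon guidance, 27 of the 28 genes listed were found in the annotation. The words ATCGAT, ATCAAT, ATTAAT and GAGAGA were counted on both strands within 50 bp of each summit and in a window of the same width 300 bp to one side, drawn with a fixed seed, by an exact McNemar test. ATTAAT is what is left of ATYRAT once ATCGAT, ATCAAT and its reverse complement are taken out. Peaks shared by replicates overlapped by at least 1 bp. Permutation tests of correlations and medians used 100000 permutations. Intervals of shares are exact 95% binomial (Clopper-Pearson) and cover counting error only. Since the depth is unknown, no interval could be set on a peak's signal.

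The gene lists, words, windows and rule for named genes were fixed before the data were examined, as were the tests of replicate overlap and correlation, promoters, distance, the X chromosome, gene lists, words and signal at promoters. The plan for words named both a mean of flanks and 1 flank drawn per peak, and the drawn flank was used. Chosen after seeing the data were the distances, positions, ranks and signal of peaks at tRNA genes, tRNA isotypes, the split of ribosomal subunits, the tests of exons, introns and intergenic sequence, and those of chromosomes other than X. The rule took the coding genes at the 20 strongest peaks, up to 4 bound members with the highest signal from each list that passed an adjusted p of 0.05, up to 10 bound pan-neuronal genes, and every CUT gene. Coding genes that share the window of a named gene are named with it. Alternatives were the conservative list, the 513 strongest peaks of the larger list, each replicate's own list, other windows, backgrounds and overlap rules. Further alternatives were chosen after seeing the data: leaving out peaks within 500 bp of tRNA, snoRNA or snRNA genes, leaving out peaks within 250 bp of tRNA genes, counting peaks in place of tRNA genes, a background without piRNA genes, controls matched on GC content in steps of 2 percentage points, and a correlation without 1 distant pair of peaks. Small RNA genes within 500 bp of the summits of named coding genes, and pseudogenes that hold them, were also looked up after seeing the data. Peaks and genes are not replicates, so p-values over them do not measure variation between animals.

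The tests were checked on simulated data. With 40 of 200 coding genes given a peak, the list test called the list in 20 of 20 draws and called a list of 200 untouched genes in 1 of 20, over 19973 coding genes. With ATCGAT placed in 102 of 1027 windows, the word test found it in 20 of 20 draws. With nothing placed, 14 of 400 word tests had a p under 0.05. Both word checks used random genome positions, so they do not cover the difference in GC content between real summits and flanks. The list check used all coding genes as background and unadjusted p-values, unlike the tests of the real lists. With 193 of 387 peaks copied between lists, the overlap came out as 49.9%. The copying fixed that share, so it checks the counting alone. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.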

Results

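CEH-44 is a homeobox transcription factor of the CUX branch of the CUT family, known to be made throughout the nervous system. Its binding was profiled in whole fourth-stage larvae with 2 biological replicates. The larger series list held 1027 peaks (median signal 75.96, quartiles 63.7 and 98.9) out of 115557 ranked candidates. The conservative series list held 1003 peaks out of 114616. Replicate 1 alone gave 387 peaks out of 63930 candidates and replicate 2 alone gave 525 out of 68342, a ratio of 1.36. The read depth of the replicates is unknown, so this ratio cannot be set against depth.

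The first question was whether the replicates marked the same sites. Of the 387 peaks of replicate 1, 258 (66.7%, exact 95% interval 61.7 to 71.3%) overlapped a peak of replicate 2, against a mean of 0.243% for random placement (permutation test, one-sided p = 0.001, the smallest that 1000 placements can give). Among replicate 1 candidates that did not pass, 0.416% overlapped a replicate 2 peak. Across the 258 overlapping peaks, signal was correlated between replicates (Spearman's rho 0.49, Pearson's r of log2 signal 0.59, two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Over candidates of all ranks the correlation was weaker (rho 0.24 over 32252 overlapping candidates of the replicates' ranked lists). Peaks are not independent replicates. One overlapping peak, at a tRNA gene on chromosome IV (2805721 to 2805964), had a signal of 2.11 in replicate 1 and 64.2 in replicate 2. The same replicate 2 peak also overlapped a stronger replicate 1 peak (2805517 to 2805760, signal 37.7) and so entered 2 of the 258 pairs. Pearson's r was 0.70 without the weaker pair, a setting chosen after seeing the data.

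With the stronger part of each replicate's list alone, the overlap was 66.8% of 193 peaks. Of all peaks of the larger series list, 259 (25.2%) overlapped peaks in both replicates' own lists, 113 overlapped replicate 1's list alone, 255 replicate 2's alone, and 400 (38.9%) neither. The larger and the conservative list shared 83.8% of the larger list's peaks.

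**Figure D1:**
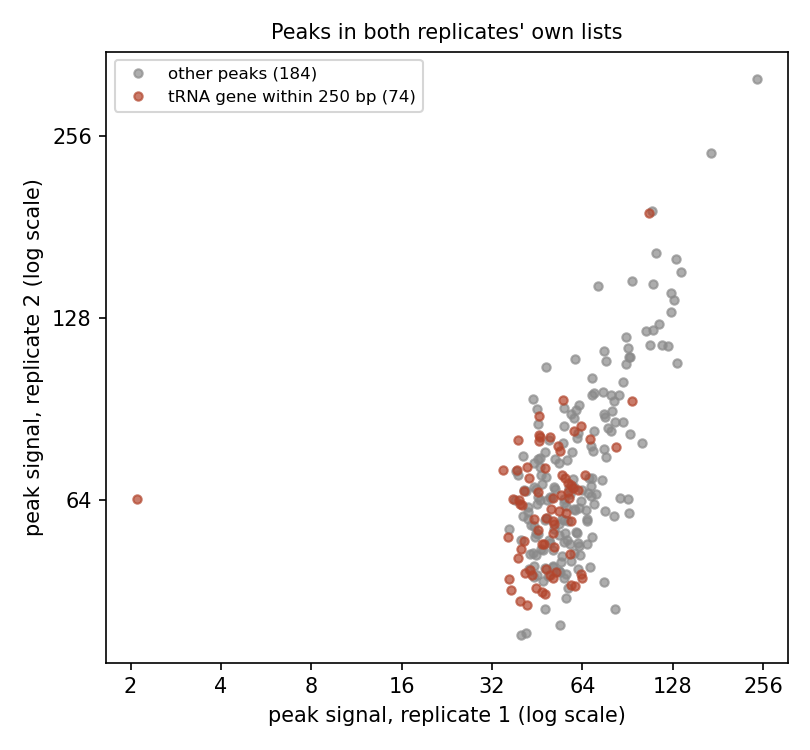
Peak signal in replicate 1 (horizontal) against replicate 2 (vertical), both on log scales without units, for the 258 peaks of replicate 1's own list that overlap replicate 2's own list. Each point is a peak, red where a tRNA gene lies within 250 bp (74 peaks), and the point at a replicate 1 signal of 2.11 shares its replicate 2 peak with the point at 37.7.

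CEH-44 peaks gathered at promoters and avoided exons of coding genes. Of 1027 summits, 444 (43.2%, interval 40.2 to 46.3%) lay in a coding promoter, against 21.2% of the 114448 candidates that did not pass (odds ratio 2.84, 95% interval 2.50 to 3.22, Fisher's exact p = 7.53e-56) and 21.004% of random positions. Exons held 36 summits (3.51%) against 28.3% of the candidates that did not pass (odds ratio 0.0920, 0.0641 to 0.128, Fisher's exact p = 4.31e-96). Introns held 286 (27.8% against 28.9%, p = 0.468) and intergenic sequence 261 (25.4% against 21.6%, p = 0.00381), by the same exact test. Adjusted over the 4 classes, these p-values were 1.51e-55, 1.72e-95, 0.468 and 0.00508. Intergenic summits did not differ in number from random positions (25.04%, two-sided permutation p = 0.809). All of these classes refer to coding genes alone, and 195 of the 1027 summits lay inside tRNA genes. The median summit lay 927 bp from the nearest coding start, against a mean of 1667 bp for random positions (permutation test, one-sided p = 0.001, the smallest possible). Without peaks near tRNA, snoRNA or snRNA genes, a setting chosen after seeing the data, the median was 521.5 bp. Of the promoter summits, 157 lay in the windows of 2 or more coding genes at once.

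The gene class with the largest share bound was tRNA genes. Of 588 tRNA genes with any candidate summit in their window, 320 were bound (54.4% against 4.14% of other noncoding genes, odds ratio 27.7, interval 23.0 to 33.3, adjusted p = 2.23e-245, Fisher's exact test). In replicate 2's own list alone the share was 36.1% (odds ratio 16.7), and in replicate 1's alone 20.8% (odds ratio 10.04). Counted by peaks, a measure chosen after seeing the data, 275 of 1027 summits (26.8%, interval 24.1 to 29.6%) had a tRNA gene within 250 bp, against 0.238% of the candidates that did not pass. In the replicates' own lists these shares were 25.8% (100 of 387) and 32.2% (169 of 525). The summits sat on the genes themselves: the median position was 17 bp downstream of the gene's start (quartiles 1 and 38 bp) in genes with a median length of 73 bp, and 195 of the 275 lay inside the gene. Peaks near tRNA genes had a median signal of 82.4 against 73.97 elsewhere (difference of median log2 signal 0.16, two-sided permutation p = 0.00027). Of the 100 strongest peaks 15 had a tRNA gene within 250 bp, and of those ranked 101 to 500, 37.25%, and of the weaker peaks 21.1%.

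Of the tRNA genes, F10C1.t1, a tRNA-Gly gene (WBGene00022983, chromosome II, 5782212 to 5782282, minus strand), had the strongest peak, with a signal of 302 in the series list, 106 in replicate 1 and 191 in replicate 2. That summit also lay in the promoter of K05F1.6, 297 bp upstream of its start. The reference sequence within 20 bp of the summit was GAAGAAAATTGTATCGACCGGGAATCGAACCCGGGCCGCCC (chromosome II, 5782203 to 5782243). The neighbouring divergent genes M02F4.t1 (tRNA-Gly; chromosome X, 3036164 to 3036235) and M02F4.t2 (tRNA-Glu; 3035976 to 3036047) shared an intergenic peak of signal 180. C53C7.t1 (tRNA-Ser; chromosome X, 13046578 to 13046659) and the divergent C53C7.t2 (tRNA-Ser; 13046366 to 13046447), the nearer of the pair to the summit, shared an intergenic peak of signal 164. All 3 of these peaks were in both replicates' own lists. Of all 320 bound tRNA genes, 85 had peaks in both replicates' own lists and 92 in neither.

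**Figure D2:**
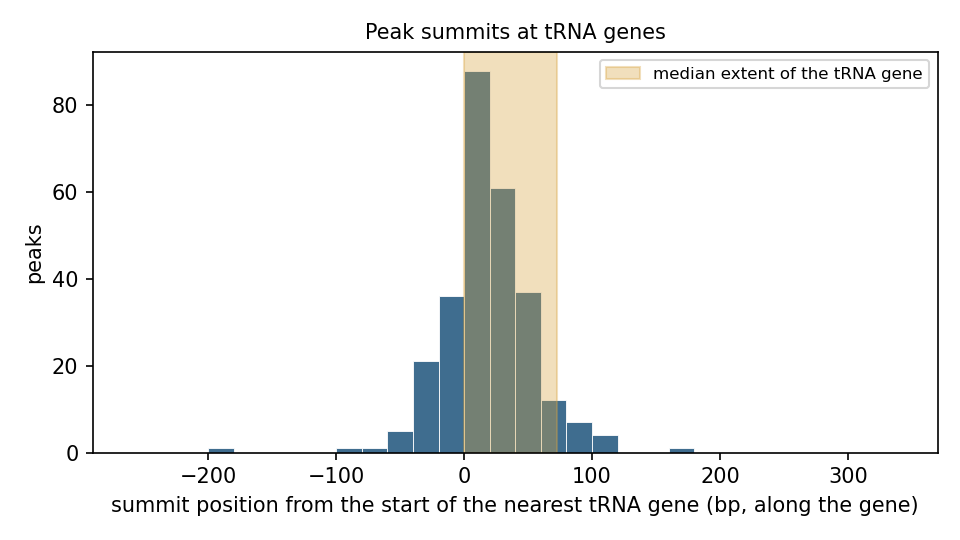
Number of peaks (vertical) by the position of the summit from the start of the nearest tRNA gene, in bp along the gene (horizontal, bins of 20 bp), for the 275 peaks of the larger series list with a tRNA gene within 250 bp. The shaded band is the median extent of the gene, 73 bp, and 195 summits lie inside their gene.

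Genes of other small nuclear and nucleolar RNAs were bound as well. Of 435 snoRNA and snRNA genes, which guide RNA modification and splicing, 116 were bound (26.7% against 5.43% of other noncoding genes, odds ratio 6.33, interval 5.01 to 7.95, adjusted p = 1.51e-43, Fisher's exact test). In the replicates' own lists alone the share was 21.99% (replicate 2) and 17.1% (replicate 1). Of the 116 bound genes, 55 had peaks in both replicates' own lists and 24 in neither. Both of the strongest peaks in the list lay on snoRNA genes of chromosome IV. T08B6.64 (WBGene00206375, 4880738 to 4880850, minus strand) had a signal of 568, with 243 in replicate 1 and 318 in replicate 2. T26A8.6 (8428614 to 8428739, minus strand) had 412, with 172 and 241. Their summit windows share an identical stretch of 63 bp found at 2 places in the genome, so reads inside it cannot be assigned to one gene. F59C6.15 (chromosome I, 10516978 to 10517150, signal 259; its peak also lies in the promoter of F59C6.18) and W03C9.9 (chromosome II, 11960898 to 11960959, signal 234) followed. microRNA genes were bound at 5.22% (12 of 230) against 6.03% (adjusted p = 1, Fisher's exact test). Of the 15697 noncoding genes tested, 6015 were piRNA genes, with a bound share of 1.06%. Without them the odds ratios were 18.2 for tRNA genes and 4.03 for snoRNA and snRNA genes, an alternative chosen after seeing the data.

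Among coding genes, ribosomal protein, splicing factor and mitochondrial respiratory chain genes were bound more often than others. Of 16131 coding genes with a candidate summit in the promoter, 598 (3.71%) were bound. Ribosomal protein genes were bound at 34.2% (26 of 76, odds ratio 14.1, interval 8.34 to 23.2, exact adjusted p = 9.23e-18), with 12 of 30 small-subunit and 14 of 46 large-subunit genes. Splicing factor genes were bound at 21.1% (8 of 38, odds ratio 7.01, 2.76 to 15.7, exact adjusted p = 0.000348). In replicate 1's own list alone 4 of 33 splicing factor genes were bound (12.1%, exact adjusted p = 0.0314). Mitochondrial respiratory chain genes were bound at 17.6% (6 of 34, odds ratio 5.61, 1.89 to 13.9, exact adjusted p = 0.00655). This list was picked by name (nuo, cox, cco, atp, cyc, isp, ucr, sdha to sdhd and mev), so chain genes named otherwise would count among the others. With each summit given to the nearest start this last list no longer passed (odds ratio 2.20, 0.562 to 6.26, exact adjusted p = 0.325). These are two-sided Fisher's exact tests adjusted over the 28 lists. Of the bound genes, 13 of the 26 ribosomal, 4 of the 8 splicing and 4 of the 6 respiratory ones had peaks in both replicates' own lists. The 26 ribosomal genes had 25 peaks and the 8 splicing genes 7, while the tests count genes.

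The strongest ribosomal protein peaks lay upstream of rpl-3 (WBGene00004414, chromosome III, peak 3867450 to 3867705, signal 240), rps-24 (WBGene00004493, chromosome IV, 385509 to 385644, signal 237), rpl-15 (signal 206, shared with K11H12.8) and rps-26 (signal 141, shared with tmem-107). The 4 summits lay at positions from -427 to -276 bp of the start. Among splicing genes the leading ones were prp-19, a ubiquitin ligase of the spliceosome (signal 287, shared with K10D2.5 and emb-1), and mog-4, an RNA helicase of the spliceosome (signal 270). The summit of the former lay at -631 bp from the start of prp-19 and at -44 bp from that of K10D2.5. The Sm protein genes snr-4 (signal 150) and snr-1 (signal 113, shared with snx-13) followed. The respiratory genes were led by the cytochrome c oxidase subunits cox-5B (signal 140) and cox-5A (signal 126), the ATP synthase subunit atp-5 (signal 115, shared with lmtr-3) and cox-6A (signal 106). Of these peaks, rps-26's lay 91 bp from the snoRNA gene F39B2.14, snr-4's 45 bp from the snRNA gene C52E4.8, and cox-6A's inside the snRNA gene F54D8.7. Heat shock protein genes passed with 3 of 13 bound (23.1%, odds ratio 7.83, 1.38 to 30.5, adjusted p = 0.0439, Fisher's exact test): the mitochondrial chaperonin hsp-60 (signal 116, shared with Y22D7AL.10), hsp-1 (signal 75.1) and the mitochondrial hsp-6 (signal 62.8, shared with C37H5.5). None of the 3 was in both replicates' own lists, and the list no longer passed under 7 of 9 other settings, among them the conservative list (6.25% bound).

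Chemoreceptor genes, which are used by sensory neurons, were bound less often than other coding genes: 7 of 947 (0.739% against 3.89%, odds ratio 0.184, interval 0.0734 to 0.383, adjusted p = 3.30e-08, Fisher's exact test). The bound members with the highest signal were sre-23 (signal 157), srx-7 (116), srh-269 (90.9) and srz-97 (81.3, shared with clec-57). The srh-269 summit lay inside the tRNA-Gln gene T03E6.t1, sre-23's 56 bp from the snoRNA gene ZK265.10, and srz-97's 23 bp from the snRNA gene F08H9.11. In replicate 2's own list alone the share was 0.322% (2 of 622, odds ratio 0.113), and in replicate 1's alone 0.693% (4 of 577, odds ratio 0.284). Without peaks near tRNA, snoRNA or snRNA genes, a setting chosen after seeing the data, 3 of 947 chemoreceptor genes were bound (0.317%).

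**Figure D3:**
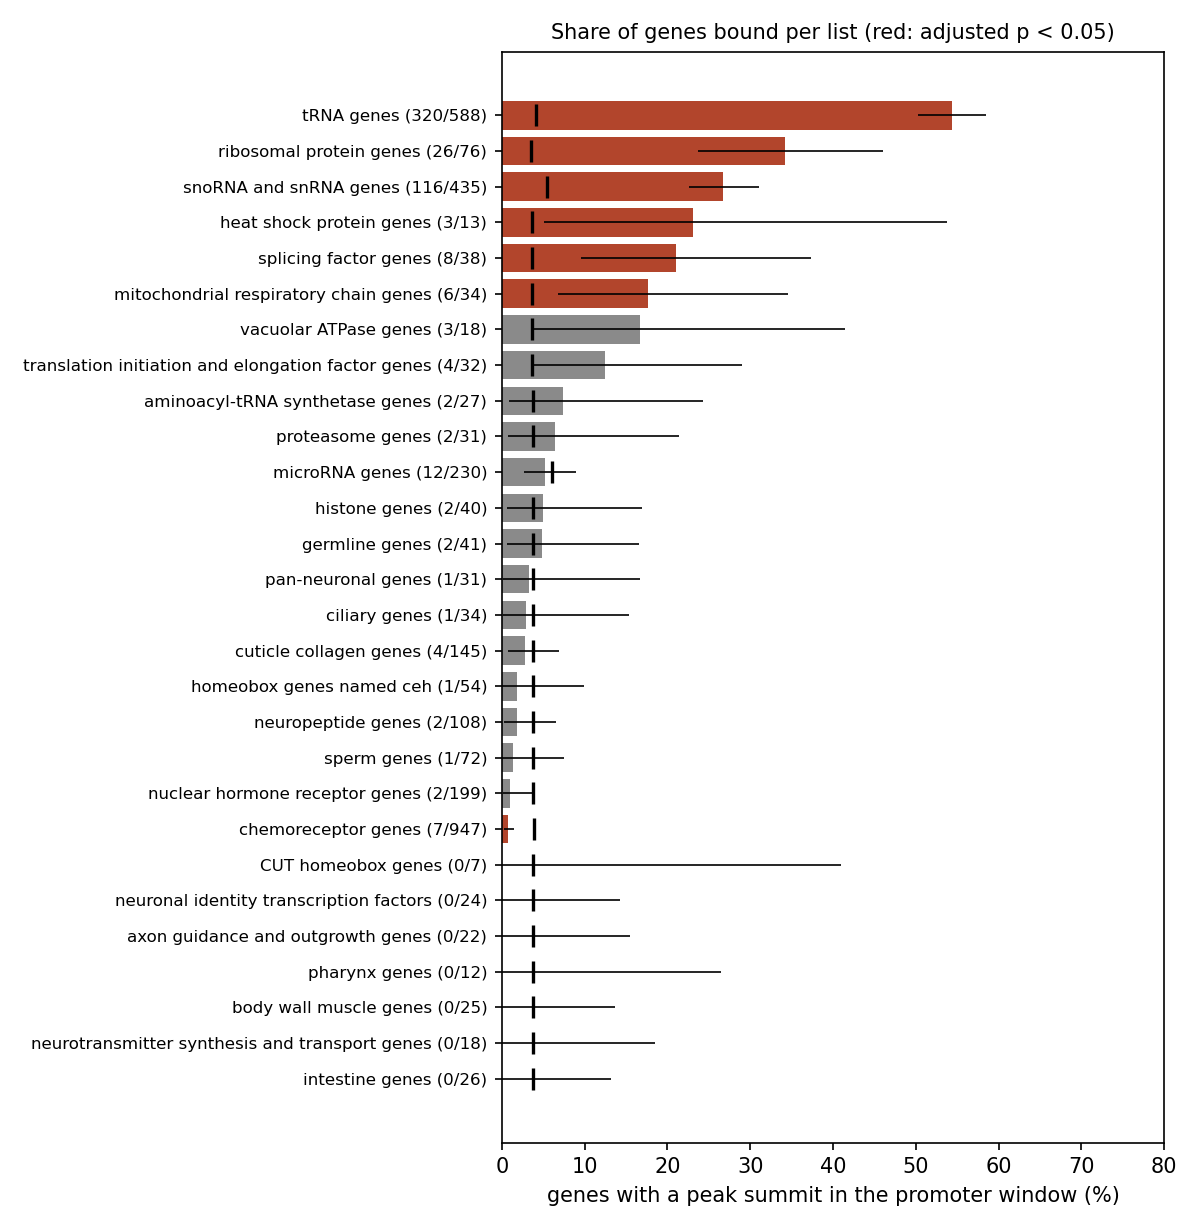
Share of genes with a peak summit in the promoter window (horizontal, percent) for the 28 gene lists, with bound and testable gene counts beside each name. Bars are shares with exact 95% binomial intervals, black ticks are the share of other genes of the class, and red marks an adjusted p under 0.05. tRNA genes reach 54.4%, ribosomal protein genes 34.2% and pan-neuronal genes 3.23%.

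Other coding genes at the 20 strongest peaks had varied known roles. Replicate signals follow in the order 1 and 2, and all of these peaks were in both replicates' own lists. The ubiquitin ligase gene eel-1 (peak on chromosome IV, 3050423 to 3050573) had signal 298, from 109 and 193. K12H4.5 (chromosome III, 8043901 to 8044046) had 293, from 136 and 153. The prp-19 peak (chromosome III, 5172610 to 5172731) also lay in the windows of K10D2.5 and emb-1. Y62F5A.12 (chromosome II, 11534936 to 11535081) had 274, and the divergent pair supr-1 and dnj-28 (chromosome I, 2996288 to 2996415) had 255. The Ras pathway scaffold gene cnk-1 (chromosome III, 10270843 to 10271098) had 237. The pair nrde-2, of nuclear RNA interference, and atad-3, a mitochondrial ATPase (chromosome II, 10248500 to 10248615) had 234. The pair tasp-1 and K01G5.10 (chromosome III, 10759123 to 10759378) had 222. Some of the strongest peaks lay partly in repeated sequence. The share of 30-base words around the summit that occur more than once in the genome had a median of 0.881% in the larger list. It was 21.6 to 38.3% for eel-1, Y62F5A.12, supr-1 with dnj-28, cnk-1 and nrde-2 with atad-3. For rps-24 and mog-4 it was 47.1% and 34.4%. It was 5.29% for prp-19 and 0% for K12H4.5, rpl-3 and tasp-1. Presence in both replicates' own lists does not exclude reads shared between repeats.

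Apart from the lower share of chemoreceptor genes, no neuronal gene list passed an adjusted p of 0.05. Of 31 testable pan-neuronal genes 1 was bound (3.23% against 3.71%, odds ratio 0.866, interval 0.0212 to 5.23, Fisher's exact p = 1). That gene was tbb-1, a beta-tubulin gene (WBGene00006536, chromosome III, peak 10742569 to 10742824, signal 64.02, rank 758), whose peak also lies in the window of rib-2 and was in neither replicate's own list. None of 18 neurotransmitter genes (upper 95% bound of the odds ratio 5.92), 22 axon guidance genes (4.75) or 24 neuronal identity transcription factor genes (4.32) was bound. Neuropeptide genes were bound at 1.85%, with flp-23 and ins-39 (odds ratio 0.488, 0.0583 to 1.82, Fisher's exact p = 0.443), and ciliary genes at 2.94%, with kap-1. These 3 members were chosen after their values were seen. The flp-23 summit lay inside the tRNA-Pro gene F22B7.t5, and kap-1's 238 bp from the snoRNA gene F56C9.12. The intervals of the pan-neuronal, neurotransmitter, axon guidance and neuronal identity lists did not exclude moderate enrichment, while the neuropeptide interval ended at 1.82.

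No list of genes of other tissues passed. None of 25 body wall muscle genes (upper 95% bound of the odds ratio 4.14), 12 pharynx genes (9.37) or 26 intestine genes (3.96) was bound, and 4 of 145 collagen, 2 of 41 germline (glh-1 and cgh-1), 1 of 72 sperm (spe-48) and 2 of 40 histone genes (his-67 and his-68, at 1 peak) were (adjusted p = 1 for each of these lists, Fisher's exact test). The col-185 summit among the collagen genes lay inside a tRNA gene.

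Other lists of broadly used genes did not pass. Proteasome (2 of 31, pas-3 and rpn-9, exact adjusted p = 0.747) and tRNA synthetase genes (2 of 27, ears-2 and mars-1, 0.673) were among them. Vacuolar ATPase genes (3 of 18, vha-1, vha-8 and vha-13, p = 0.0273) and translation factor genes (4 of 32, iff-2 and eif-3.B, C and E, p = 0.0295) did not pass after adjustment (0.0919 for both, Fisher's exact test), nor did nuclear hormone receptor genes (2 of 199, nhr-142 and nhr-255, p = 0.0365, adjusted 0.102). With the window of 2000 bp upstream these 3 lists passed (exact adjusted p = 0.0317, 0.0421 and 0.00843, the last one lower), which made 10 lists in place of 7. Of the homeobox genes named ceh, a list that also holds the CUT genes with such names, 1 of 54 was bound. It was ceh-2, with its summit inside the tRNA-Leu gene C27A12.t1. The nhr-255 summit lay 18 bp from a tRNA gene. The members named here were chosen after their values were seen.

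The tagged gene itself, ceh-44 (WBGene00000464, chromosome III, 2530613 to 2546420, plus strand), had no summit in its promoter window. A peak of signal 63.2 lay in an intron, 4811 bp downstream of the start (2535296 to 2535551), and replicate 2's own list held it at 2535312 to 2535555 with signal 46.04. The reference sequence within 20 bp of the series summit was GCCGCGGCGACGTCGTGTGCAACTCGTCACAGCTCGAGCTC (2535404 to 2535444). A peak at -1788 bp from the start (2528697 to 2528952, signal 69.02) lay in the promoter windows of ndua-8, rbc-2 and Y54F10AM.15. Of the other CUT genes, none of ceh-21, ceh-38, ceh-39, ceh-41, ceh-48, ceh-49 and dve-1 had a promoter peak that passed (0 of the 7 testable CUT genes, ceh-44 included, upper 95% bound of the odds ratio 18.1). ceh-38 came closest, with a candidate of signal 58.3 at a −log10 IDR of 1.91 (chromosome II, 6951496 to 6951751). ceh-39 had an intergenic peak at -2666 bp from its start (chromosome X, 1858710 to 1858965, signal 74.3), outside the window and inside the tRNA-Glu gene T26C11.t1.

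**Figure D4:**
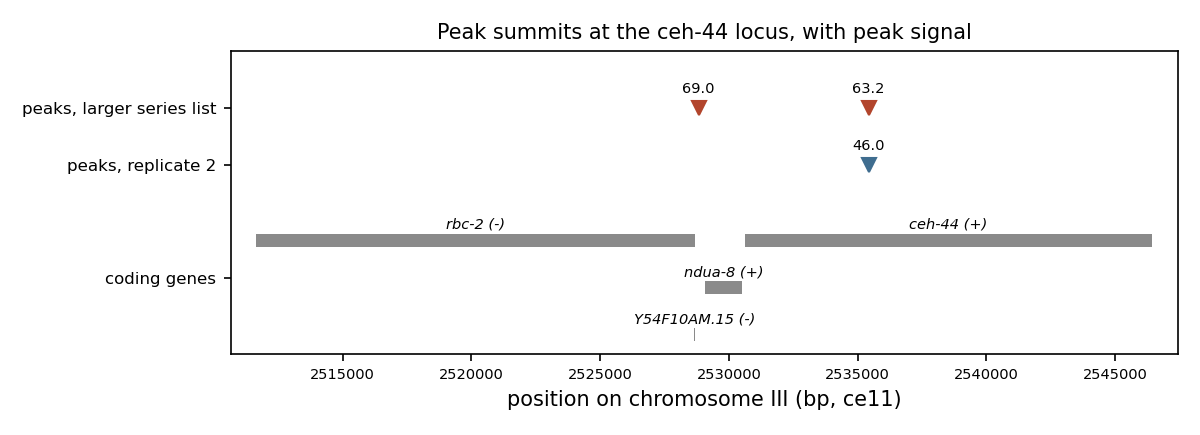
Map of the ceh-44 locus on chromosome III, with position in bp on ce11 (horizontal). Grey bars are coding genes with their strand, and triangles are peak summits with their signal, 69.02 and 63.2 in the larger series list and 46.04 in replicate 2's own list; replicate 1's own list had none here.

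The word ATCGAT, the core that CUX proteins are known to bind, was not more frequent at summits. It lay within 50 bp of 33 of 1027 summits (3.21%, interval 2.22 to 4.48%) against 52 flanking windows (5.06%; exact McNemar adjusted p = 0.0475). This lower share was not past the threshold with the other flank (exact adjusted p = 0.160), the conservative list (0.105), replicate 1's own list (0.243), or windows of 25 bp (0.0660) and 100 bp (0.0504) either side. It was past it in the 513 strongest peaks and in replicate 2's own list (0.0226 for both). ATCAAT, the ONECUT core, was found at 4.77% of summits and 10.4% of flanks (exact adjusted p = 3.87e-06), and ATTAAT at 2.34% and 8.86% (9.22e-11). Without peaks near tRNA, snoRNA or snRNA genes, a setting chosen after seeing the data, the ATCAAT difference was not past the threshold (6.06% against 8.70%, exact adjusted p = 0.114). GAGAGA was more frequent at summits, 14.8% against 6.23% (exact adjusted p = 6.46e-10). Summit windows had a mean GC content of 49.7%, flanks 35.6% and candidates that did not pass 39.1%. Against candidates matched on GC content, a control chosen after seeing the data, GAGAGA was again more frequent at summits (14.8% against 8.07%, two-sided resampling permutation of 1000 control sets, adjusted p = 0.00799, the smallest possible). For ATCGAT the summits then lay 0.313 percentage points above the controls (same permutation, adjusted p = 0.569). The lower share of ATCAAT at summits also ended (-0.579 points, permutation adjusted p = 0.569), and ATTAAT became more frequent at summits than in controls (2.34% against 1.37%, permutation adjusted p = 0.0280).

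Promoter peaks were not detectably stronger than other peaks (median signal 77.9 against 74.4, difference of median log2 signal 0.07, two-sided permutation p = 0.0805). Over chromosomes, X held 208 peaks (20.3%, interval 17.8 to 22.8%) against 17.7% of bases (exact binomial p = 0.0333, adjusted over the 6 chromosomes 0.0666) and 13.7% of coding genes (p = 6.77e-09). The difference from bases was not past the threshold with the conservative list (19.4%, exact p = 0.147), the 513 strongest peaks (18.1%, p = 0.772), replicate 2's own list (19.6%, p = 0.252) or replicate 1's (17.8%, p = 0.947). Chromosome V, tested after seeing the data, held 153 peaks (14.9% against 20.9% of bases, exact adjusted p = 7.40e-06). X carries 276 of the 612 tRNA genes (45.1%), and without the peaks near tRNA genes its share was 10.6%, below its share of bases (exact binomial p = 9.86e-08). That alternative was chosen after seeing the data.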

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

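Tests chosen only after the result was seen were those on highly transcribed genes and on ATCGAT at tRNA genes. The tests on tRNA gene copies, on pan-neuronal genes and on repeated sequence were written before their results were seen.

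Of 1109 ranked peaks that passed the IDR threshold of the larger series list, 82 (7.39%) were absent from it. The gene list tests above used these 82 only as candidates that made a gene testable, not as binding. The strongest absent peak, on chromosome X, had a signal of 2132.7 against 568 for the strongest kept peak, and 11 of the 20 strongest passing peaks were absent. Repeated sequence is a candidate cause of the absence. Around the summits of absent peaks a median of 89.4% of 30-base words occurred more than once in the genome, against 0.881% for kept peaks (two-sided permutation p = 1e-05, the smallest possible). Among kept peaks 102 (9.93%) were mostly repeated words, so repeats alone do not separate the sets, and no biological explanation was tested.

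Peaks gathered at tRNA genes. Reads shared between identical tRNA genes were one explanation. Of 131 tRNA genes with a full sequence found once in the genome, 39.7% (exact 95% interval 31.3 to 48.6%) were bound, against 4.14% of other noncoding genes. An identical copy was thus not needed for a gene to be called bound. Only exact full-length copies were counted, so reads shared between nearly identical genes are not excluded. A summit in the window may also belong to a neighbouring tRNA gene: the 320 bound tRNA genes had 268 peaks. Genes with copies were bound more often (268 of 457, 58.6%, Fisher's exact p = 0.000148), which leaves a contribution open. Binding through ATCGAT is argued against for most of the 275 tRNA gene peaks, since 1.82% held it within 50 bp of the summit (0.593 to 4.19%). The comparison with flanks (exact McNemar p = 0.774) cannot decide whether it is enriched there, since the flanks were not matched on GC content. Signal at highly transcribed or open loci whatever the tagged protein stays open. Without peaks near small RNA genes, ribosomal protein genes had an odds ratio of 12.4 (7.05 to 21.01). This cannot decide the question, since 21 of the 26 genes bound in the main result stayed bound. Binding of CEH-44 at these promoters would also give such a value. Splicing factor, respiratory chain and heat shock genes passed too, the last in few other settings. Histone (2 of 40, odds ratio 1.37, 0.160 to 5.32), proteasome (2 of 31, 1.79, 0.207 to 7.12) and tRNA synthetase genes (2 of 27, 2.08, 0.238 to 8.38) did not. These intervals do not exclude strong enrichment. Vacuolar ATPase (5.22, 0.965 to 18.5) and translation factor genes (3.73, 0.947 to 10.7) passed with the window of 2000 bp upstream but not in the main result. Control data were not used here.

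Pan-neuronal genes were not bound more often than other genes. Binding below the threshold cannot be told apart from none: the median of their strongest ranked signal, 25.7, lay at percentile 78.8 of 10000 random lists, whose median was 23.8. Binding outside the promoter window also stays open. With each summit given to the nearest coding start, 4 of 33 were bound, with an odds ratio of 2.28 (0.580 to 6.50, Fisher's exact p = 0.118), and 2 of those 4 peaks lay at a pseudogene or a snoRNA gene. Neurons are only some of the cells in a whole larva, and dilution of their signal was not tested.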

How the results depend on the processing

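Leaving out peaks near tRNA or other small RNA genes, the controls matched on GC content, the background without piRNA genes, counting peaks for tRNA genes, and the correlation without 1 pair were chosen after seeing the data. Of 150 alternatives over 24 results, 121 counted as the same, 20 lost the threshold, 1 gained it and 8 reversed. For counts of peaks or of passing lists, the same means a similar number. The window of 2000 bp upstream thus counted as the same although 10 lists passed in place of 7. For the peaks shared by the series lists, the same means a value inside the main interval. For all other results, it means the same direction and side of the threshold. The tRNA (10 alternatives), snoRNA and snRNA, ribosomal protein, splicing and chemoreceptor lists and GAGAGA (9 each), genomic location (7), distance (5) and replicate overlap (3) kept both throughout, though shares moved: without a replicate, tRNA genes had 20.8 to 36.1% and chemoreceptor genes 0.322 to 0.693%. Where a value below moved, the cause was not tested unless stated.

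With the conservative list, the share of peaks on X was 19.4%, heat shock genes were bound at 6.25%, pan-neuronal genes at 3.70% (reversed) and ATCGAT differed by -1.50 percentage points. X, heat shock genes and ATCGAT lost the threshold there. With the 513 strongest peaks X had 18.1% and heat shock genes 7.69% (threshold lost for both), and the promoter difference in log2 signal, 0.0963, passed the threshold. Leaving out each replicate gave X 17.8 to 19.6%, heat shock genes 9.09 to 15.4% and ATCGAT -3.05 to -2.07 points. X and heat shock genes lost the threshold without either replicate, and ATCGAT without replicate 2.

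With the window of 500 bp upstream, heat shock genes were bound at 18.2% (threshold lost) and pan-neuronal genes at 4.35% (reversed). With 2000 bp 10 lists passed in place of 7, with vacuolar ATPase, translation factor and nuclear hormone receptor genes added, and pan-neuronal genes reached 5.88% (reversed). Against all annotated genes heat shock genes had 13.6% (threshold lost). With nearest starts heat shock genes had 20% and mitochondrial genes 11.8% (threshold lost for both), and pan-neuronal genes 12.1% (reversed). No pan-neuronal value passed the threshold, so its reversals are changes of sign around the background.

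For ATCGAT, 25 bp gave -1.27 points, 100 bp -2.43 and the other flank -1.27 (threshold lost for each). Without peaks near small RNA genes it was -1.40 and ATCAAT -2.64 (threshold lost for both), and pan-neuronal genes had 3.23% (reversed). With controls matched on GC content ATCGAT was 0.313 (reversed, not past the threshold), ATTAAT 0.962 (reversed, and past the threshold in the other direction) and ATCAAT -0.579 (threshold lost). Without peaks near tRNA genes X had 10.6% (reversed), since X carries 45.1% of tRNA genes. Read depth is unknown, so its limit on these values could not be set.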

Other observations

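The genes and peaks named here were chosen after their values were seen.

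The peak ranked 20 lay on rpr-1, the RNA gene of ribonuclease P, which trims tRNA precursors (chromosome I, 13463910 to 13463988, signal 216, in both replicates' own lists). By isotype, 11 of 13 tRNA-Cys genes and 4 of 20 tRNA-His genes had a summit within 250 bp, but no isotype differed from the others after adjustment (lowest adjusted p 0.122, Fisher's exact test).

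With each summit given to the nearest coding start, the pan-neuronal genes reached were unc-104, unc-41, unc-31 and unc-33. The unc-104 intron peak (chromosome II, 7001503 to 7001758, signal 156) has its summit inside the 72 bp pseudogene WBGene00023260. The unc-41 intron peak (chromosome V, 9970190 to 9970445, signal 102) has its summit 47 bp from the snoRNA gene C27H6.5. The unc-31 (signal 64.002) and unc-33 (signal 54.7) peaks were intergenic, with no tRNA, snoRNA or snRNA gene within 500 bp.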
